A study of Bos taurus with 89 samples.

How the data were processed

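Luminal epithelial cells were collected from the endometrium of beef cows with a cytology brush, and RNA captured by its poly-A tail was sequenced, per the labels' protocols. Each library is labelled with its cow, its treatment (H for high and L for low progesterone before estrus), its day after estrus (4, 7 or 14) and a value named p4. That value was read as the progesterone concentration on the sampling day, because the design text describes blood sampling for progesterone on those days. The labels give no unit for it.

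The deposited files hold whole-number counts of reads per gene, without normalization, 1 file for each of 89 libraries and 27570 Ensembl gene IDs in each file. Per the submitters' processing notes, FastQC 0.11.7, Trim Galore 0.4.4, HISAT2 and HTSeq were used with the bovine assembly ARS-UCD1.2. The versions of HISAT2 and HTSeq, the annotation release and whether strand was used in counting are not given in the sources used here. Reads that match several near-identical gene copies can be lost or split in counting, and without a stated strand setting overlapping and antisense genes cannot be told apart, so values of such genes are uncertain. Every file listed the same genes, no pair of files held identical values (0 pairs), and 3745 genes had no count in any library. Totals ran from 9450680 to 27757904 counts per library. Intervals and standard errors below cover the spread between libraries and counting error, and not errors of alignment. Within a day, and in counts summed per cow, each cow counts once. Standard errors of the day comparisons treat repeated libraries of a cow as independent. A standard error marked as over genes does not cover the spread between cows.

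Groups were formed from the treatment and day labels. Counts were tested in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16, after filterByExpr with a minimum count of 10, TMM scaling, and robust estimation of dispersions. P-values were adjusted by the Benjamini-Hochberg procedure over all genes tested, and a gene was called at an adjusted p under 0.05. A log2 fold change is given with its standard error, computed as its size over the square root of the F statistic. H and L were compared on each day in a fit of that day's libraries alone, where each cow appears once, and in counts summed per cow over the 16 cows with all 3 days. Days were compared in a fit of all 6 groups, averaging H and L with equal weight, and the same groups gave an F-test of whether H minus L differed between days. The slope of each gene on log2 progesterone was tested within each day, with treatment as a covariate. Progesterone itself was compared between H and L by two-sided permutation tests with 100000 resamples (scipy 1.17.1). Levels are given as CPM, counts scaled to a common library total corrected by the TMM factors.

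The cow labels tie libraries of different days together. After removing group means, the 66 pairs of libraries from the same cow had a median correlation across genes of 0.325 and 57 of them exceeded 0.1, against a median of -0.0134 for 2554 pairs from different cows. Of 84 libraries whose cow was also sampled on another day, 53 had a library of the same cow as the closest among libraries of other days. The main design carried no block for the cow. Fits with the cow as a fixed block, and as a random block in limma 3.58.1 with voom, were run as alternatives.

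The files do not pair gene IDs with symbols, and 0 of the IDs matched a symbol in the reference table used here. Genes are therefore given by ID, without positions or functions. The rule fixed for named genes took, per comparison, called genes that carry a symbol and have a mean of at least 5 CPM in the higher group, the 6 with the largest rise and the 6 with the largest fall, plus members of 37 gene lists and 3 receptors. Without symbols it was applied to IDs, and reduced to the 2 largest rises and the 2 largest falls, or to the 2 IDs with the smallest p in each direction where nothing was called. The tests of the 37 lists, the receptors, and an alternative with markers of leukocytes, stroma and endothelium as covariates were not run. A share of RNA from cells other than luminal epithelium was therefore not measured.

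Alternatives were other scaling factors, no filter or a filter at 1 CPM, non-robust dispersions, DESeq2 1.42.0, limma voom with sample quality weights, a minimum log2 fold change of 1, 2 surrogate variables (sva 3.50.0), other sets of libraries and covariates, and the cow as a block. For each count of genes, up to 100 splits of the libraries or cows were compared with the real one. The steps were tested on simulated counts drawn with the means, totals and dispersions of the real libraries, in which 200 genes were changed. At a 2-fold change the tests recovered 76.1% of changed genes between H and L on day 4, 62.7% on day 7, 68.7% on day 14 and 61.2% in the summed cows. They recovered 92.5% for day 7 against day 4, 79.1% for day 14 against day 7, 76.1% for day 14 against day 4 and 55.2% for the interaction. For a doubling of progesterone, the figures at a 2-fold change were 91.0% on day 4, 68.7% on day 7 and 28.4% on day 14. The largest share of false calls in any of these simulations was 4.02%. The simulated libraries were independent, without the correlation between libraries of a cow, so this share does not hold for the fits over days without a block. Genes were also drawn independently of each other, so the share and the recovery rates are not shown to hold for the fits of single days. There, shuffles of H and L gave up to 824, 1423 and 606 calls on days 4, 7 and 14. Of the shuffles of progesterone on day 7, 29 gave at least 1 call, and the highest gave 302.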

Results

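The libraries profiled luminal epithelial cells, the cell layer that lines the uterine cavity and meets the embryo first, in beef cows with some Bos indicus ancestry. Cows had been given 1 of 2 hormone protocols that set progesterone before estrus high (H) or low (L). H cows received a new intravaginal progesterone insert and gonadotrophin-releasing hormone. L cows received an insert that had been used before, the same releasing hormone and prostaglandin F2α, a hormone that regresses the corpus luteum. Cells were sampled in the cycle that followed, on days 4, 7 and 14 after estrus. There were 12 H and 18 L libraries on day 4, 14 H and 20 L on day 7, and 11 H and 14 L on day 14. The replicates of a group are separate cows, 39 in all (15 H and 24 L), and 16 cows (8 of each treatment) were sampled on all 3 days. Totals ranged from 9450680 to 27757904 counts per library, 16880 to 19067 genes had at least 1 count, and the 10 most abundant genes of a library held between 2.77% and 10.3% of its counts.

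Progesterone on the sampling day rose over the cycle in both treatments and did not separate them. H and L cows averaged 0.846 ± 0.471 (SD, n = 12) and 0.980 ± 0.432 (SD, n = 18) on day 4, in the unstated unit of the labels. On day 7 the means were 3.04 ± 0.815 (SD, n = 14) and 3.51 ± 1.12 (SD, n = 20), and on day 14 they were 5.78 ± 1.07 (SD, n = 11) and 6.74 ± 2.32 (SD, n = 14). Two-sided permutation tests of H against L gave p = 0.435, 0.187 and 0.216 on days 4, 7 and 14 (0.435, 0.323 and 0.323 after Benjamini-Hochberg adjustment over the 3 days). The 95% interval of H minus L ran from -0.486 to 0.218 on day 4, from -1.15 to 0.205 on day 7 and from -2.43 to 0.498 on day 14.

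**Figure D1:**
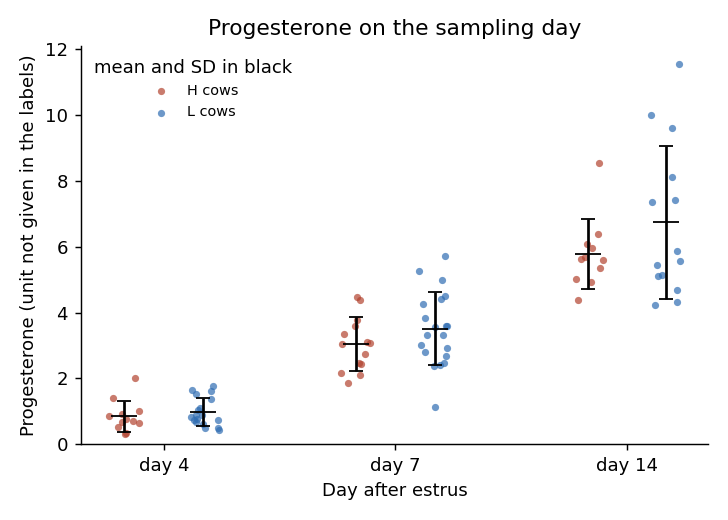
Progesterone on the sampling day (vertical axis, unit not given in the labels) for each cow on days 4, 7 and 14, with H cows in red and L cows in blue and the mean ± SD in black. The means of both treatments rise from under 1 on day 4 to 5.78 and 6.74 on day 14, and the points of H and L overlap on each day.

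The leading principal components followed the day after estrus and not the treatment. The first principal component held 16.3% of the variance of log2 CPM, of which 60.7% lay between days, 23.7% between cows of a group (37 degrees of freedom) and 0.641% between treatments. The second held 12.2%, of which 71.1% lay between days and 0.256% between treatments. Over all 16369 genes of the 6-group fit, day took 21.1% of the sum of squares with 2 degrees of freedom and treatment with its interaction 2.43% with 3. Cows within groups took 45.9% with 37 degrees of freedom, a number that by itself raises such a share, and 30.5% was left within cows. By the root mean square distance of log2 CPM over all these genes, 6 of the 89 libraries, from 4 cows, lay nearer to the mean of another day than to that of their own. These were L day 4 replicate 4, L day 7 replicates 2 and 3, H day 7 replicate 10, and L day 14 replicates 2 and 3.

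**Figure D2:**
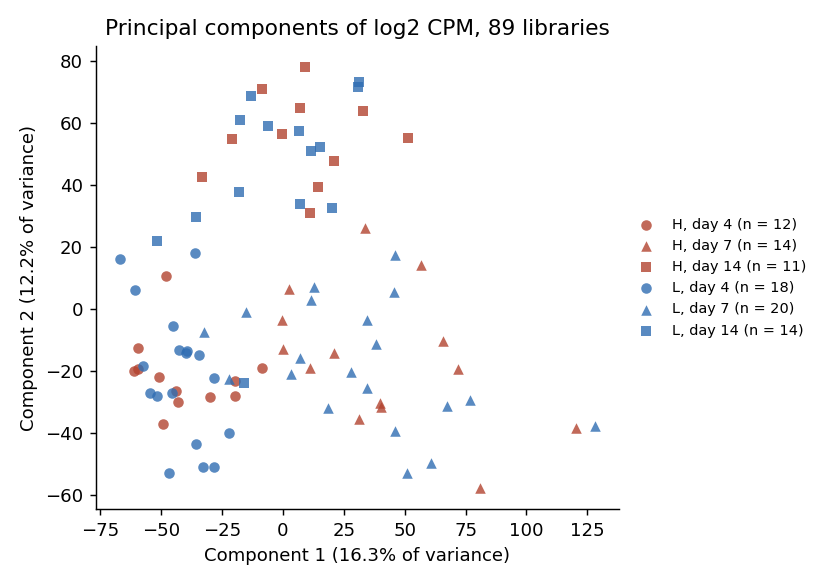
Principal components 1 and 2 of log2 CPM for 89 libraries, with colour for treatment (H red, L blue) and shape for day (circles day 4, triangles day 7, squares day 14). The components hold 16.3% and 12.2% of the variance, the shapes fall into largely separate areas with some libraries of different days side by side, and the colours mix.

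Between day 4 and day 7 a large part of the genes tested changed, in both directions. The share of RNA from other cells was not measured, so a change in the cells collected cannot be told apart from one within the epithelium. ENSBTAG00000034674 rose from 0.311 ± 0.411 CPM (SD, n = 30) to 117 ± 176 CPM (SD, n = 34), a log2 fold change of 8.44 ± 0.644 (SE), and was higher on day 7 in 25 of 25 cows sampled on both days. ENSBTAG00000007392 rose from 0.0180 ± 0.0433 to 10.9 ± 16.4 CPM, by 8.91 ± 0.880 on the log2 scale, and was higher in 24 of 25 cows with 1 tie. Its day 4 libraries held 10 counts in all, so the size of this rise is uncertain. ENSBTAG00000018214 fell from 85.8 ± 68.1 to 4.14 ± 7.94 CPM, with a log2 fold change of -4.42 ± 0.534, and was lower in 24 of 25 cows. ENSBTAG00000037644 also ranked among the falls, at -4.29 ± 1.00, but L day 4 replicate 1 held 98.3% of its day 4 level, and without that library the log2 fold change was -1.09 with an adjusted p of 0.246. It was lower on day 7 in 16 of 25 cows and higher in 4, and its log2 fold change was -2.68 with the cow as a replicate block. The adjusted p-values of the first 3 genes were 2.72e-19, 2.22e-14 and 4.55e-11 (edgeR's quasi-likelihood test). In all, 4073 genes rose and 3691 fell among 16369 tested, and 1224 of the rises and 613 of the falls had a log2 fold change of at least 1 in size. Scaling to the library total alone shifted the median log2 fold change of all genes to -0.186, against -0.00314 with TMM, and gave 2515 rises and 6403 falls, so that 28.2% of calls rose instead of 52.5%.

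From day 7 to day 14 the balance among large changes turned to loss. ENSBTAG00000031052 dropped from 35.5 ± 43.8 CPM (SD, n = 34) to 0.0560 ± 0.198 CPM (SD, n = 25), a log2 fold change of -10.31 ± 0.840 (SE), and ENSBTAG00000040279 dropped from 11.9 ± 13.5 to 0.0929 ± 0.146 CPM, at -6.99 ± 0.604. Each was lower on day 14 in 20 of the 21 cows sampled on both days. Their day 14 libraries held 24 and 38 counts in all, so the sizes of these falls are uncertain. For ENSBTAG00000031052 the highest day 14 library was L day 14 replicate 3, at 0.951 CPM, and the day 14 median was 0. ENSBTAG00000046768 climbed from 3.77 ± 9.89 to 466 ± 584 CPM, at 7.18 ± 0.735, and ENSBTAG00000013980 from 0.863 ± 0.790 to 46.0 ± 41.4 CPM, at 5.74 ± 0.456. They were higher on day 14 in 20 and 19 of the 21 cows. The adjusted p-values of these 4 genes lay between 2.96e-18 and 1.81e-13 (edgeR's quasi-likelihood test). The test called 2849 rises and 2812 falls, and among changes of at least 1 on the log2 scale there were 496 rises and 890 falls.

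Day 14 against day 4, the widest interval, gave 3703 rises and 3188 falls. ENSBTAG00000007392 reached 69.7 ± 82.0 CPM (SD, n = 25) on day 14 from 0.0180 ± 0.0433 CPM (SD, n = 30) on day 4, a log2 fold change of 11.55 ± 0.932 (SE) with an adjusted p of 5.14e-18. With 10 counts in all on day 4, the size of this rise is uncertain too. ENSBTAG00000046768 was low on day 4, at 0.538 ± 2.69 CPM, and rose by 10.90 ± 0.974 on the log2 scale (adjusted p = 5.77e-16). Most of its day 4 mean came from L day 4 replicate 4, at 14.8 CPM, with the next library at 0.385 CPM and a median of 0. Each of these genes was higher on day 14 in 19 of 20 cows with both days and tied in the remaining cow. The largest falls were uneven between cows. ENSBTAG00000006599 had a log2 fold change of -8.24 ± 1.07, with 70% of its day 4 level in H day 4 replicate 2, and ENSBTAG00000039787 one of -5.93 ± 1.15, with 95.3% in L day 4 replicate 14. Without those libraries the values were -6.23 and -3.05, with adjusted p-values of 3.27e-08 and 0.00518. They were lower on day 14 in 15 and 11 of 20 cows, higher in 2 and 1 and tied in 3 and 8. Their size depended on the method, at -7.46 and -3.21 with the cow as a replicate block, -3.79 and -1.75 with it as a random block, -3.36 and -2.22 in limma voom with quality weights, and -16.01 and -3.10 in DESeq2. Scaling to the library total alone gave 1912 rises and 5929 falls (24.4% of calls rose, against 53.7%), with the median of all genes at -0.181.

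**Figure D3:**
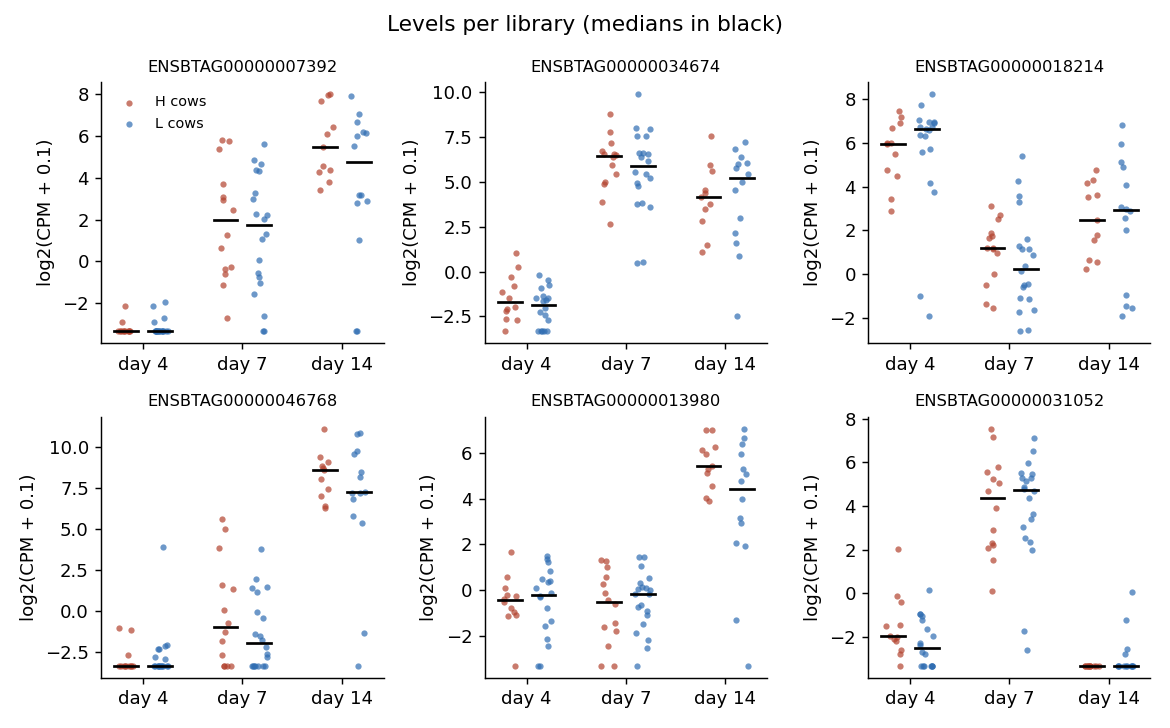
Levels per library, as log2(CPM + 0.1), of 6 genes named for the day comparisons, on days 4, 7 and 14, with H cows in red, L cows in blue and group medians in black. In each panel the H and L points of a day overlap, and the medians of both treatments move the same way between days, except that those of ENSBTAG00000013980 stay nearly level from day 4 to day 7.

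Day 7 was a turning point for many genes. Of the 16369 genes, 1799 rose from day 4 to day 7 and then fell to day 14, against 700 if the calls of both steps were independent, and 1009 fell and then rose, against 642. Only 395 genes rose at both steps and 172 fell at both, against 709 and 634. The steps share the day 7 libraries, which alone pulls estimates toward opposite signs. Across genes, which are not independent replicates, the log2 fold changes of the 2 steps had a covariance of -0.228 and r = -0.403, against -0.020 and -0.449 in counts simulated with that sharing and no change between days. These simulated libraries carried no correlation within cows, and the split given next still leaves cows shared between days. When the day 7 libraries were split so that each step used its own part, 1336 and 1313 genes rose and then fell in the 2 assignments (expected 409 and 498), and 626 and 563 fell and then rose (expected 315 and 403). In the same assignments 166 and 382 genes rose at both steps (expected 389 and 454) and 64 and 147 fell at both (expected 331 and 441). Another 1879 genes rose and 2510 fell by day 7 with no call afterwards, 1445 rose and 841 fell after day 7 with no call before, and 6319 had no call at either step.

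**Figure D4:**
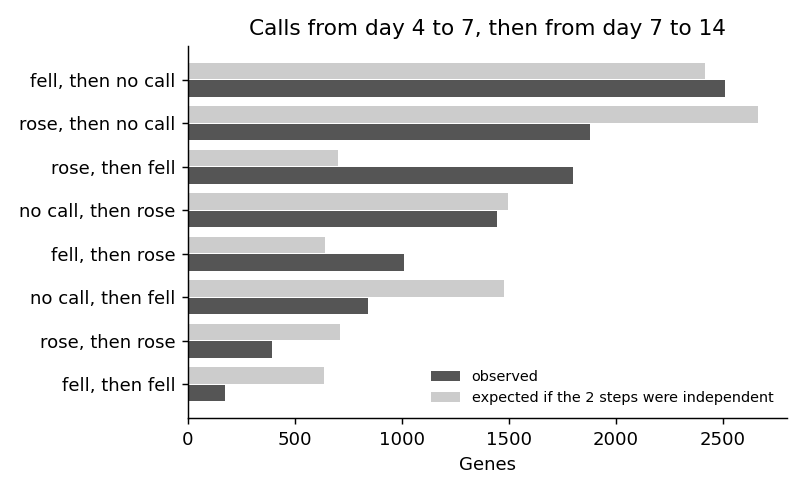
Number of genes (horizontal axis) for each pair of calls, day 4 to 7 and then day 7 to 14, with a call in at least 1 step, with observed numbers in dark grey and the numbers expected if the steps were independent in light grey. Genes that rose and then fell number 1799 against 700 expected, and those that rose at both steps 395 against 709.

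The changes over the cycle were correlated between H and L cows. The log2 fold changes of the 2 treatments, which come from separate cows, correlated across genes at r = 0.856 for day 7 against day 4, 0.820 for day 14 against day 7 and 0.844 for day 14 against day 4, where genes are not independent replicates. Neither treatment was fitted alone: each was a contrast of the 6-group fit, with shared filter, scaling and dispersions. In these contrasts H cows gave 4507, 3420 and 3900 genes and L cows 5760, 2934 and 4088. Of these, 3483, 2069 and 2648 were called in both, with the same direction in 3482, 2068 and 2646. The test of whether H minus L differed between days called 9 genes in edgeR (466 at an unadjusted p under 0.05, of 16369). DESeq2 called 10, of which 3 were shared, and limma voom with quality weights called 0. With the cow as a replicate block the count was 0, with 649 at an unadjusted p under 0.05, and with the cow as a random block it was also 0, with 551. Without the 6 libraries nearer to another day it was 2, both among the 9.

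Between H and L, edgeR's quasi-likelihood test called no gene in the fits of single days. On day 4 the smallest adjusted p, 0.0626, belonged to ENSBTAG00000037811, at 52.0 ± 121 CPM in H (SD, n = 12) and 4.81 ± 2.43 CPM in L (SD, n = 18). Its log2 fold change was 3.43 ± 0.616 (SE), and H day 4 replicate 4 held 69.2% of the H level; without that library the value was 1.87. ENSBTAG00000017718 was at 9.65 ± 19.1 CPM in H and 0.875 ± 1.08 CPM in L (adjusted p = 0.203), with a log2 fold change of 3.44 that was 2.44 without H day 4 replicate 6, which held 54.0% of the H level. ENSBTAG00000007816 was at 3.02 ± 1.30 CPM in H and 44 ± 67.6 CPM in L (log2 fold change -3.86 ± 0.883, adjusted p = 0.480), while the medians were 3.03 and 3.88 CPM. ENSBTAG00000024984 was at 1.32 ± 0.656 CPM in H and 2.35 ± 0.810 CPM in L (adjusted p = 1.00). There were 0 calls among 15351 genes, with 472 at an unadjusted p under 0.05. DESeq2 called 2 genes, ENSBTAG00000037811 and ENSBTAG00000007816, limma voom with quality weights 0, and edgeR with all 6 groups in 1 fit 5.

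On day 7 the comparison of H and L again gave 0 calls, with 596 of 15170 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.964. ENSBTAG00000054942 was at 25.6 ± 10.9 CPM in H (SD, n = 14) and 15.5 ± 7.28 CPM in L (SD, n = 20), a log2 fold change of 0.73 ± 0.204 (SE). ENSBTAG00000027213, at 1.75 ± 0.485, rested on H day 7 replicate 2, without which it was 0.028. ENSBTAG00000005353 was at 2.40 ± 1.43 CPM in H and 10.7 ± 15.9 CPM in L, at -2.14 ± 0.535, and ENSBTAG00000021211 had a log2 fold change of -1.69 ± 0.422. The adjusted p was 0.964 for these 4 genes. DESeq2 called 2 genes, both lower in H and 1 of them ENSBTAG00000005353 (adjusted p = 0.0352), limma voom with quality weights 0, and edgeR with all 6 groups in 1 fit 2.

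On day 14 edgeR gave 0 calls among 14817 genes, with 467 at an unadjusted p under 0.05. ENSBTAG00000012280 and ENSBTAG00000014329 had log2 fold changes of 4.23 ± 0.985 and 4.60 ± 1.09 (SE), but H day 14 replicate 11 held 95.4% and 96.1% of their H levels. Without that library the values were -0.063 and 0.055. ENSBTAG00000007816 stood at 3.16 ± 1.09 CPM in H (SD, n = 11) and 46.5 ± 65.5 CPM in L (SD, n = 14), at -3.87 ± 0.864, and ENSBTAG00000001359 at 1.55 ± 0.632 and 5.09 ± 4.85 CPM, at -1.72 ± 0.453. The adjusted p was 1.00 for these 4 genes. DESeq2 called 2 genes, both lower in H and 1 of them ENSBTAG00000007816 (adjusted p = 0.000801), limma voom with quality weights 0, and edgeR with all 6 groups in 1 fit 6. In the 16 cows sampled on all 3 days, summed counts gave 0 calls in edgeR among 16584 genes, with 508 at an unadjusted p under 0.05, against 0 in limma voom with quality weights and 3 in DESeq2, among them ENSBTAG00000007816 at a log2 fold change of -4.03. The median standard error of the log2 fold change was 0.156 on day 4, 0.180 on day 7, 0.203 on day 14 and 0.194 in the summed cows.

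On day 7 the slope on progesterone, at a fixed treatment, passed the test for 12 of 15170 genes in edgeR, all with a negative slope, in a result that rested on 1 cow. At an unadjusted p under 0.05 there were 1808. ENSBTAG00000000828, at 22.3 ± 29.9 CPM (SD, n = 34), had a log2 change of -2.06 ± 0.356 (SE) per doubling of progesterone, and ENSBTAG00000031453 one of -1.67 ± 0.265. Their adjusted p-values were 0.00886 and 0.00509 (edgeR's quasi-likelihood test). Without L day 7 replicate 3, which had the lowest progesterone, 0 genes were called by edgeR, with 987 at an unadjusted p under 0.05, and without L day 7 replicate 6, which had the highest, 7 were. L day 7 replicate 3 is among the 6 libraries nearer to another day, and without the 6 the count was also 0, with 1042 at an unadjusted p under 0.05. Its progesterone was 1.14, within the day 4 range of 0.30 to 2.02, ENSBTAG00000018214 was at 42.9 CPM against a day 7 median of 1.97, and ENSBTAG00000031052 at 0.0651 against 25.6. The day 14 library of the same cow, L day 14 replicate 3, had ENSBTAG00000046768 at 0.297 CPM against a day 14 median of 258. With progesterone not logged edgeR called 0 genes, with 1461 at an unadjusted p under 0.05. DESeq2 called 22 genes, 6 with positive and 16 with negative slopes and 10 of them shared, and limma voom with quality weights 2, both with positive slopes and neither shared. On day 4 edgeR called 0 genes, with 1350 of 15351 at an unadjusted p under 0.05, against 5 in DESeq2 and 0 in limma voom. On day 14 it called 0, with 518 of 14817, and so did DESeq2 and limma voom.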

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

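The runs with each gene's highest value replaced and without libraries nearer to another day were chosen after the result was seen. The H minus L difference itself differed between days for 9 genes in the F-test over all 6 groups. By pairs of days it differed for 5 genes between day 7 and day 4, each with a more negative value on day 7. It differed for 3 genes between day 14 and day 4, each with a more positive value on day 14, and for 0 between day 14 and day 7. ENSBTAG00000001191 had the smallest adjusted p, 0.000605, with H minus L at 5.96 on day 4, -1.07 on day 7 and 0.59 on day 14 on the log2 scale. Its highest library, H day 4 replicate 4, was at 305 CPM and the next at 36.9 CPM. ENSBTAG00000014329 had values of -1.18, 0.35 and 4.61, with H day 14 replicate 11 at 828 CPM and the next library at 42.3 CPM. These IDs were picked after their values were seen. When the highest value of each gene was replaced by the mean of the rest of its group, 9 genes were again called, and 0 of them were among the first 9. With the cow as a block the count was 0, and without the 6 libraries nearer to the mean of another day it was 2, both among the 9. Chance cannot be excluded: 11 of 100 assignments of treatment to whole cows, the real one included, gave at least 9 genes, and the highest of the others gave 61. Of the others, 72 gave at least 1 gene, with a median of 2. None of the groups had 10 libraries or fewer, so outlying libraries within groups were not tested for.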

How the results depend on the processing

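Every alternative was fixed before the data were examined, except the runs with no scaling beyond the library total, with each gene's highest value replaced, without the cow of lowest or highest progesterone, without libraries nearer to another day, and with the library total as a covariate, which were chosen after seeing the data. The 3 day comparisons kept counts within 1.5 times under the other tools, filters, scaling factors and surrogate variables and with the cow as a block. The paired fits (cow as a replicate block) gave 8643, 5526 and 7537 genes for day 7 against 4, 14 against 7 and 14 against 4, of which 7290, 4879 and 6375 were among the 7764, 5661 and 6891 called without it. Without the cow of lowest day 7 progesterone, whose libraries stood apart from their days, the counts without a block were 7894, 5936 and 7081, and the interaction 8. Without the 6 libraries nearer to the mean of another day, a choice that itself favours day differences, the counts were 7973, 5936 and 7257, the interaction 2, and H against L 0 on each day and in the summed cows. A minimum log2 fold change of 1 left 1837, 1386 and 1745 genes. Contrasts of H cows only, within the same 6-group fit, gave 4507, 3420 and 3900. Those of L cows only gave 2934 and 4088 for the last 2. Each rests on fewer libraries. Between H and L, the count of 0 became 2 (day 4), 2 (day 7), 2 (day 14) and 3 (summed cows) in DESeq2, and 5, 2 and 6 on days 4, 7 and 14 with all 6 groups in 1 fit. The smallest adjusted p on day 4 ranged from 7.81e-06 to 1.00 over its alternatives. The interaction count of 9 became 0 with limma voom with quality weights, 0 with 2 surrogate variables, 0 with the cow as a replicate block and 0 with it as a random block. The slope on progesterone gave 4 genes on day 4, 50 on day 7 and 1 on day 14 without a filter, and 5 on day 4 and 22 on day 7 in DESeq2. On day 7 it gave 2 genes in limma voom, 0 with progesterone not logged, 0 without the cow of lowest progesterone, 0 without the 6 libraries and 7 without that of highest. The cause was not tested, except that the last 3 runs leave out libraries. Progesterone kept its direction and its side of 0.05 with medians or logs. ENSBTAG00000027213 (H minus L, day 7) turned to -0.10 in cows with all 3 days. That run leaves out, among others, H day 7 replicate 2, which held 71.7% of the H level. Without that library alone the value was 0.028. ENSBTAG00000012280 (day 14) turned to -0.064 in DESeq2 and -0.027 with its highest value replaced. Of the other alternatives for 24 named gene values, 327 kept direction and side, 9 gained and 3 lost the call. No library was under the planned minimum total, so that alternative gave no value, and marker covariates were not run for lack of symbols.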

Other observations

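The tests chosen only after their results were seen are the other splits of the H and L libraries on single days and of the days, the shuffles of progesterone values, and the run with the library total as a covariate. Libraries of the same cow resembled each other across days. After removing group means, 154 of 16369 genes had an intraclass correlation within cows over 0.75 across the 3 sampling days, and 1969 exceeded 0.5 (34 cows with 84 libraries). Shuffling cows within groups 100 times gave at most 0 and 9 such genes. The median over all genes was 0.265, against at most 0.0891 in the shuffles. The shuffles break up cows and any processing shared by a cow's libraries alike, so they cannot tell these apart.

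ENSBTAG00000007816 was the 1 gene with an unadjusted p under 0.01 and the same direction between H and L on all 3 days, with H minus L at -3.86, -3.10 and -3.87 on the log2 scale on days 4, 7 and 14. In 6 cows, all L and 4 of them with more than 1 library, every library held at least 63 CPM. In 30 cows every library was at or below 8.21 CPM, and 3 cows had libraries on both sides of 10 CPM. Of these, 1 L cow went from 169.7 CPM on day 4 to 3.22 and 1.32 CPM on days 7 and 14, and another L cow from 1.89 CPM on day 7 to 117.9 CPM on day 14. The third, an H cow, only just passed the limit, from 1.09 CPM on day 4 to 10.47 CPM on day 7. The intraclass correlation of the gene within cows was 0.655. A candidate explanation is a fixed difference between cows that fell unevenly over the treatments, but it does not account for the changes in those 2 L cows. The 3 libraries on which these changes turn, L day 4 replicate 4, L day 7 replicate 3 and L day 14 replicate 3, lay nearer to the mean of another day than to that of their own. ENSBTAG00000018214 was at 0.159 CPM in the first (day 4 median 80.9) and at 42.9 CPM in the second (day 7 median 1.97), and ENSBTAG00000046768 at 0.297 CPM in the third (day 14 median 258). Progesterone was 0.90, 1.14 and 5.58 with these libraries. The day 4 and day 14 values lie within the range of their labelled day (0.30 to 2.02 and 4.23 to 11.54), and the day 7 value is the lowest of that day. Progesterone was measured in blood and does not show which RNA a library holds. Whether the libraries carry the right label therefore stays open, and the 2 cows do not exclude a fixed difference. The same doubt holds for 1 of the 6 cows with every library at or above 63 CPM. Its L day 7 replicate 2 and L day 14 replicate 2, at 147.2 and 93.06 CPM, also lay nearer to the mean of another day. In L day 14 replicate 2 ENSBTAG00000046768 was at 0 CPM. The number of such genes gives treatment no backing. Of 100 assignments of treatment to whole cows, the real one included, 37 gave at least 1 such gene, and the highest of the others gave 12. That number does not weigh the smaller unadjusted p-values of this gene (0.000125, 0.000368 and 0.00013 in edgeR's quasi-likelihood test). DESeq2 called it on day 4, on day 14 and in the summed cows, and edgeR in the main fits did not. What sets the level in these cows stays open.

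The 12 genes that fell with progesterone on day 7 also fell over the cycle: their mean log2 fold change for day 14 against day 4 was -1.74 ± 0.330 (SE over genes), and 11 of them were called as falling. A hypothesis is that cows with more progesterone on day 7 were further along the change from day 4 to day 14. The value has the sign it predicts but does not test it. The genes were called only with L day 7 replicate 3, which had the lowest progesterone and lay nearest to the mean of day 4. Genes chosen through such a library tend to be higher on day 4, and the standard error does not cover the spread between cows. Library depth was tested with the library total as a covariate. In this run 12 of the 12 genes kept an unadjusted p under 0.01 and their sign. They had been picked in the same libraries at an unadjusted p of at most 3.76e-05 (edgeR's quasi-likelihood test). Their calls also rested on 1 library, so the run says little about depth. In that run 10 genes were called, 9 of them among the 12. Chance cannot be excluded, because 7 of 100 pairings of progesterone values with libraries gave at least 12 genes and the highest of the others gave 302. The count also fell to 0 without L day 7 replicate 3, which lay at 0.0866 on the way from day 4 to day 14 described next.

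That hypothesis was tested on whole day 7 libraries by their position along the change between the other days, from 0 to 1, over the 500 genes with the smallest p for that change. Day 7 libraries lay at 0.538 ± 0.242 (SD, n = 14) in H and 0.455 ± 0.203 (SD, n = 20) in L on the way from day 4 to day 14. Their position correlated with log2 progesterone at r = 0.282 after removing treatment means (permutation p = 0.103, adjusted over 3 days 0.309) and at a Spearman rho of 0.229 (permutation p = 0.194, adjusted 0.466), with r = 0.143 without the 2 libraries farthest from the median progesterone. A positive r had been fixed beforehand as the prediction for days 4 and 14 as well, and it was not met. Their axes join the other days, so being further along the cycle has no set direction on them and the values do not test the hypothesis. The same r was -0.081 for day 4 libraries between days 7 and 14 (permutation p = 0.672, adjusted 0.672, rho -0.113, permutation p = 0.558, adjusted 0.558, and r = -0.0102 without the 2 farthest) and -0.141 for day 14 libraries between days 4 and 7 (permutation p = 0.565, adjusted 0.672, rho -0.226, permutation p = 0.311, adjusted 0.466, and r = -0.373 without the 2 farthest). The day 7 correlation did not pass its test, before or after adjustment, and the hypothesis stays open. The 95% interval of H minus L lay within 0.2 of the way on day 4 (-0.0391, -0.113 to 0.0349) and day 14 (0.0404, -0.0710 to 0.152). These values hold only for a shift along the axis between the other days and do not measure an advance of H or L in the cycle. On day 7 a shift of that size cannot be told from none (0.0829, -0.0800 to 0.246). Permutation p-values of H minus L were 0.307, 0.288 and 0.494 on days 4, 7 and 14 (adjusted 0.460, 0.460 and 0.494).

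Differences between H and L did not repeat between days beyond what shared cows give. Mean H minus L correlated across genes at r = 0.0394 between days 4 and 7, 0.220 between days 7 and 14 and 0.155 between days 4 and 14. Assigning treatment to whole cows at random 1000 times gave medians of 0.224, 0.258 and 0.216, and the observed values lay within the central 95% of those assignments.

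Other splits of the libraries tested each count. For the days, chance can be excluded: 1 of 100 shuffles of day labels within treatment, the real one, gave as many genes for each comparison, 7764 for day 7 against day 4 (highest other 1049), 5661 for day 14 against day 7 (81) and 6891 for day 14 against day 4 (130). Between H and L, with 0 genes called by edgeR, every split gives at least as many by construction (100 on day 4, 100 on day 7, 100 on day 14 and 99 of the summed cows), so the count decides nothing about chance. Of the other splits 8, 12, 3 and 2 gave any gene, and the highest gave 824, 1423, 606 and 1. The few splits that call many genes point to a structure of those libraries, whose nature was not tested.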
